A study of Mus musculus with 35 samples.

How the data were processed

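The authors profiled H3K4me3, H3K27me3 and H3K36me3 with input libraries by CATCH-seq. Per the labels, H3K4me3 libraries numbered 4 in c13, 2 in c34, 2 at E18.5 and 1 in GV oocytes. H3K27me3 libraries numbered 2 in c7, 2 in c13, 2 in c34, 2 at E18.5 and 1 in GV oocytes, and H3K36me3 libraries 2 at each of 4 stages. The deposited files were 13 peak lists in an other unit than counts, namely peak positions in base pairs, with no score, height or p-value. Per the file headers each list held a chromosome, a start and an end. Starts counted from 0, ends were inclusive, and both lay on a grid of 1 kb for H3K4me3 and 10 kb for the other marks. The submitters' processing notes name Trim Galore 0.4.1, cutadapt 1.9.1, Bowtie2 2.3.4.1, SAMtools 1.7, Picard 2.18.23, bedtools 2.29.2, deepTools 3.5.0, SICER 0.0.41 and MACS2 2.1.1 and the builds GRCm38.p3 and mm10. Which tool called which peaks, the threshold, the use of input and the pooling of libraries are not given in the sources used here. Read depth is unknown, so a list can be longer because its libraries were deeper or its threshold lower, and grid and gap settings limit how narrow or close peaks can be.

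Each list was placed on a 1 kb grid over 19 autosomes and X, 2613 Mb in all. Coordinates in the text are 1-based on GRCm38. Gene positions came from the RefSeq gene table of GRCm38.p6, whose primary assembly is that of the deposited peaks. As a check, H3K4me3 peaks contained 47.5% of gene ends in c13, 39.5% in c34, 34.4% at E18.5 and 48.0% in GV oocytes, against 20.9%, 17.4%, 9.46% and 31.2% of points 100 kb away. Sets were compared by the Jaccard index in base pairs, by the shares of each list in the other and by covered length. Standard errors came from leaving out each of 20 chromosomes in turn, and 95% intervals used a t quantile of 2.09. They cover variation along the genome and neither replicate nor counting error. Chance overlap came from 1000 circular shifts of a list along each chromosome, with no p-value. Overlap beyond chance was the shared length above that of independent placement, as a share of the largest excess that the covered lengths allow.

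Because the gene table gives no strand, genes were marked by a peak of at least 1 bp within 1 kb of either annotated end, a departure from the planned gene start. Bodies were marked by H3K36me3 from 20% coverage. Random gene lists, 10000 per list, were matched on gene length in 5 groups, and the planned matching on promoter CpG content was not done since no genome sequence was used. A percentile is the place of a list among its random lists, a description and not a p-value. Gene lists (oocyte factors, meiosis, germline, pluripotency and early germ cell, developmental regulators, H3K27me3-dependent imprinted, maternal germline imprinted, chromatin and methylation machinery, ovarian somatic cells, housekeeping) and gene families by symbol were fixed, with the comparisons and the named gene rule, before the data were examined. All 209 list entries matched the gene table, 1 through an older symbol, and 3 were not protein coding and were left out of counts. Named genes were list members marked at 1 of the compared stages, at most 8 per list, the 5 genes per direction with the largest difference in coverage of windows of 5 kb around both ends, up to 4 members marked at all or no stages, and genes in the 3 widest peaks of a list. Where many genes tied, they were ordered by symbol. Some genes that met the rule are not reported here, and ties of H3K27me3 and H3K36me3, which ran from 99 to 7575 genes, were not named.

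The set arithmetic was tested on simulated data: over 20 pairs of simulated lists the largest error of the Jaccard index was 0 and 18 of 20 jackknife intervals held the value drawn. The simulated peaks were separate 1 kb bins placed at random, with the same expected overlap on every chromosome. How often the intervals hold for wide or clustered peaks was therefore not tested. For gene ends, 200 of 200 genes given a peak were recovered. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives changed the chromosomes, peak width, number of peaks, gaps, overlap measure, bins, domain width, windows and body share. Requiring both gene ends, keeping only genes apart from others, wider merging, overlap beyond chance and leaving out peaks of 1 Mb or more were chosen after seeing the data. Input libraries have no list of their own and were not used here, and peaks on Y were left out of all comparisons.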

Results

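Histone H3 modifications were mapped in female mouse germ cells at 5 stages by CATCH-seq, a native chromatin immunoprecipitation for small cell numbers in which chromatin is cut with micrococcal nuclease and carrier DNA limits losses. The marks were H3K4me3, which lies at active and poised promoters, H3K27me3, which is laid down by Polycomb repressive complexes, and H3K36me3, which covers transcribed gene bodies. 3 stages were grown from the mouse embryonic stem cell line H18, which carries Prdm1-mVenus and Dppa3-ECFP reporters: c7 oogonia-like cells, c13 oocyte-like cells and c34 oocyte-like cells. Animals gave the other stages, E18.5 fetal oocytes from mice with the same reporters and germinal vesicle (GV) oocytes from BDF1 mice. The title of the study names GV oocytes made from embryonic stem cells without ovarian somatic cells, so the comparisons asked how the cultured stages resembled oocytes from animals.

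The labels listed 35 libraries, of which 9 were H3K4me3, 9 H3K27me3, 8 H3K36me3 and 9 input. The deposited peaks formed 13 lists, 1 per stage and mark, with H3K27me3 alone at c7. Depth was unknown and there were no replicate lists, so no difference could be set against replicate spread. Intervals below were 95% jackknife intervals over 20 chromosomes and measured variation along the genome only. A gene was called marked by H3K4me3 or H3K27me3 when a peak lay within 1 kb of either annotated gene end, and by H3K36me3 when peaks covered at least 20% of its body.

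H3K4me3 covered 254 Mb in c13, 259 Mb in c34, 135 Mb in E18.5 oocytes and 645 Mb in GV oocytes. The median GV peak was 11 kb wide, against 4 kb in c13, 5 kb in c34 and 4 kb at E18.5. H3K27me3 covered 892 Mb in c7, 1053 Mb in c13, 927 Mb in c34, 1033 Mb at E18.5 and 720 Mb in GV oocytes. H3K36me3 covered 1122 Mb in c13, 929 Mb in c34, 633 Mb at E18.5 and 997 Mb in GV oocytes. Protein-coding genes made up 40.1% of the chromosomes compared. They held 64.4% of the H3K36me3 length in c34 and 61.8% in GV oocytes, against 54.6% in c13 and 39.0% at E18.5, where random placement gave 39.3%. In c13, 79.8% of the H3K36me3 length lay in peaks of 1 Mb or more, against 34.4% at E18.5, 4.77% in c34 and 4.80% in GV oocytes.

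**Figure D1:**
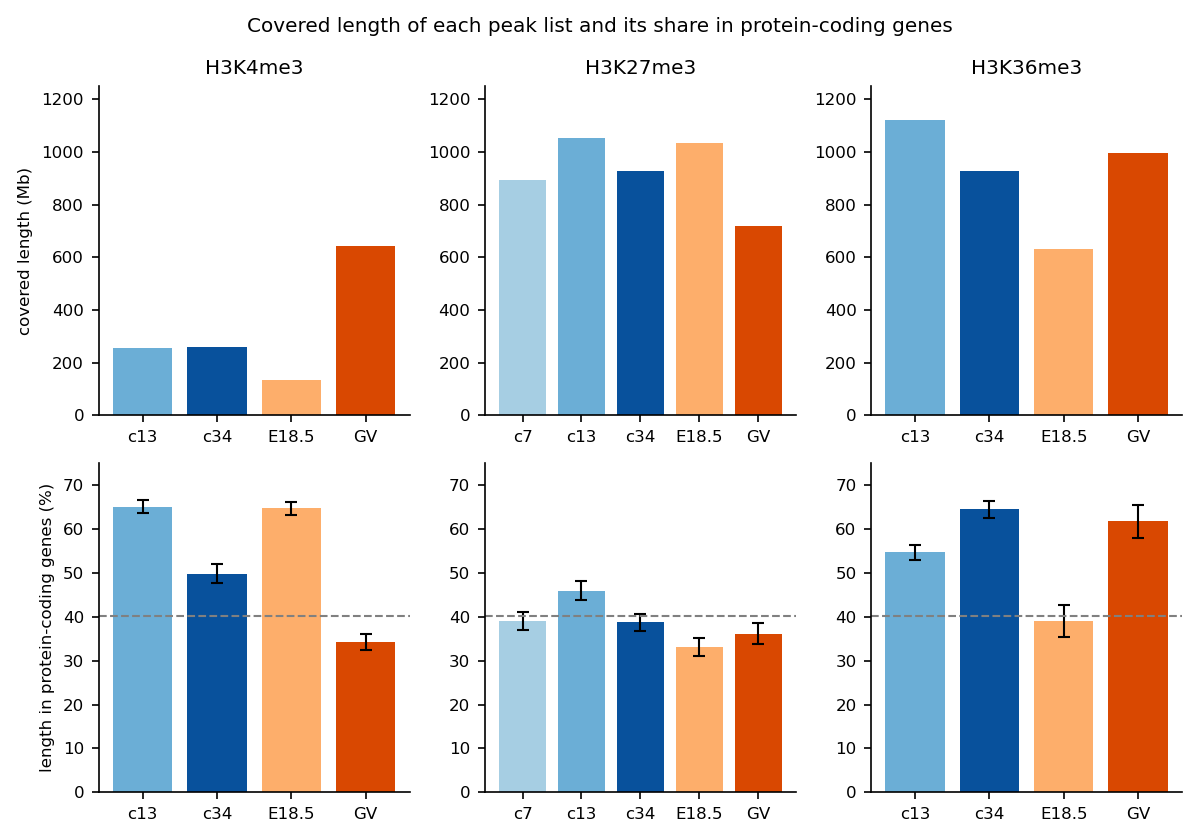
Upper bars give the covered length (Mb) of each peak list and lower bars the percentage of that length in protein-coding genes, by stage and mark, with 95% jackknife intervals and a dashed line at the genome share of 40.1%. GV oocytes had the longest H3K4me3 coverage, 645 Mb, of which 34.3% lay in genes, and the E18.5 H3K36me3 list lay at the genome share with 39.0%.

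The latest cultured stage was compared with the full-grown oocyte for H3K4me3. Genes of the oocyte programme carried the mark at both stages: 24 of 25 oocyte factors were marked in c34 and 23 in GV oocytes, where random gene lists of matched length gave 16.2 and 18.2. Those marked at every stage with a list included the transcription factors Nobox, Figla, Sohlh1 and Sohlh2. Npm2, a chaperone of sperm and oocyte chromatin, was marked in c34 and not in GV oocytes by the 1 kb rule, although the wider windows of 5 kb around its ends held 6000 bp of peaks in c34 and 6198 bp in GV oocytes. The NLR family gene Nlrp14 was marked at no stage. Of 24 meiosis genes, 19 were marked in c34 and 21 in GV oocytes. Syce3, a component of the synaptonemal complex, the meiotic cohesin gene Rec8 and Spo11, which makes meiotic DNA breaks, were marked in GV oocytes only, and Syce1 in c34 only. Of 16 germline genes, 13 were marked in c34 and 14 in GV oocytes, where Tex101 was the addition. Ddx4, Dazl, Tdrd1 and Tdrd9, which encode RNA-binding and piRNA pathway proteins, were marked at every stage.

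Of 30 developmental regulators, 28 had H3K4me3 in c34 and 26 in GV oocytes, with Isl1 and En1 among those in c34 only and Gata4 in GV oocytes only. Of 20 pluripotency and early germ cell genes, 15 were marked in c34 and 18 in GV oocytes, with Tdgf1, Fgf4 and Utf1 the additions. Of 15 genes with H3K27me3-dependent imprinting, 9 were marked in c34 and 8 in GV oocytes. Etv6 and Inhbb were marked in c34 only, and Jade1 in GV oocytes only. Of 15 imprinted genes with maternal germline methylation, 10 were marked in c34 and 8 in GV oocytes. Zrsr1, Nnat and Peg3 were marked in c34 only, and Zdbf2 in GV oocytes only. Among 22 genes of chromatin and DNA methylation machinery, 20 were marked in c34 and 22 in GV oocytes, the additions being Tet1, a 5-methylcytosine dioxygenase, and Dnmt3a, a de novo DNA methyltransferase. All 20 housekeeping genes, among them Actb, Gapdh, Hprt and Tbp, were marked at both stages. Of 19 genes of ovarian somatic cells, 13 were marked in c34 and 12 in GV oocytes. Inha, Fst and Wt1 were marked in c34 only, and Nr5a1 and Gata4 in GV oocytes only.

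Across 21631 protein-coding genes, 13836 were marked by H3K4me3 in both c34 and GV oocytes, 597 in c34 only and 2343 in GV oocytes only. The widest excess of c34 over GV around gene ends was at Sfi1 (chromosome 11, 3131850 to 3203347), with 17653 bp of its end windows of 5 kb on each side covered in c34 and 0 bp in GV oocytes. Ddx54 and Atp6v1b1 were also among the genes with the largest excess in c34. In the opposite direction 100 genes tied at 20000 bp in GV oocytes and 0 bp in c34, of which Abcg5, a sterol transporter, Ace3 and Adam11 were among the alphabetically first. Of the c34 H3K4me3 length, 75.7% lay in GV peaks, against 25.3% after random shifts, while 30.4% of the GV length lay in c34 peaks.

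The Jaccard index, the shared length over the joint length, was 0.277 ± 0.00825 (jackknife SE) between c34 and GV oocytes and 0.173 ± 0.00517 between c34 and E18.5 oocytes. The difference of 0.104 had an interval of 0.0872 to 0.120, which excluded 0. Covered length was lower in c34 than in GV oocytes by a log2 ratio of -1.32 (-1.43 to -1.20). With peaks at or above the median width of their own list, 3466 genes were marked in c34 only and 3677 in GV oocytes only. That cut was 5 kb in c34 and 11 kb in GV oocytes. Such unlike cuts do not show whether narrow peaks carried the excess of genes marked in GV oocytes only.

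**Figure D2:**
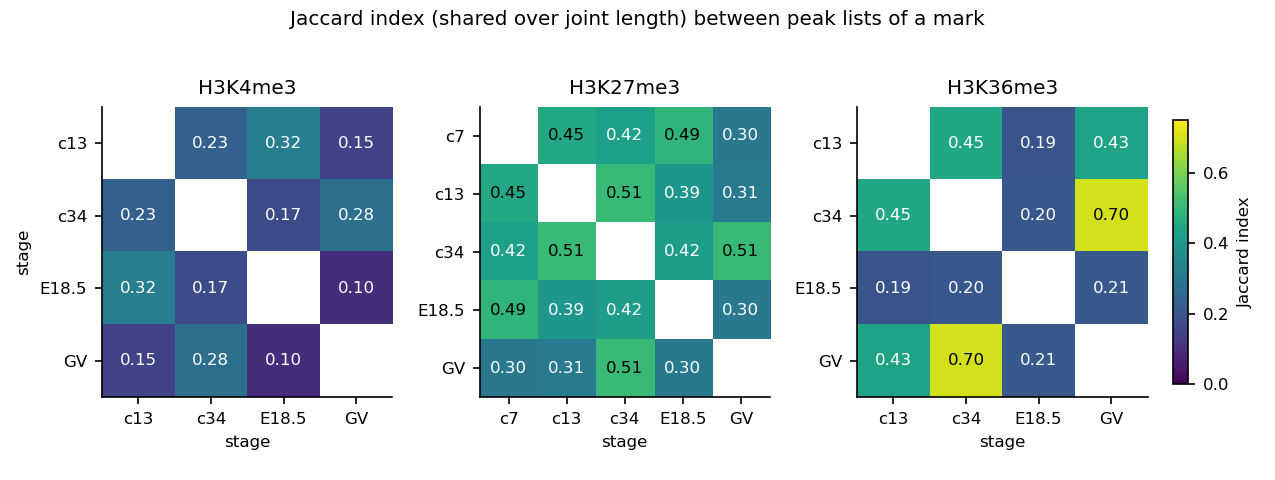
Each cell gives the Jaccard index, a ratio without units, between the peak lists of the stages on its axes, in 1 panel per mark; the diagonal is left blank. The c34 list had its highest index with the GV list for H3K4me3 (0.277) and H3K36me3 (0.698), and E18.5 had an index near 0.2 with every stage for H3K36me3.

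For H3K27me3, most oocyte factors were unmarked in both c34 and GV oocytes. Of 25, 4 were marked in c34 and 3 in GV oocytes, where random lists gave 10.9 and 7.03. Btg4, a regulator of maternal mRNA decay, and the transcription factor gene Lhx8 were marked in c34 only, and H1f8, the oocyte linker histone gene, in GV oocytes only. Genes with H3K27me3-dependent imprinting carried the mark at both stages: 14 of 15 were marked in c34 and 15 in GV oocytes, against 7.15 and 4.58 in random lists, Bbx being the addition. Since this list is defined by dependence on H3K27me3, its number in GV oocytes is no independent result. Only 1 of 15 genes imprinted through maternal germline methylation was marked at each stage. Peg3, Zrsr1, Impact and Inpp5f were marked at none of the 5 stages.

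Developmental regulators were marked in c34 in 30 of 30 cases and in GV oocytes in 22. Gata6, T, Sox17, Olig2, Hoxb1, Gsc and Neurog1, transcription factor genes of early lineages, were among those marked in c34 only. At Sox17 the windows around the gene ends held 16499 bp of H3K27me3 peaks in c34 and 0 bp in GV oocytes. Among pluripotency and early germ cell genes, 14 were marked in c34 and 8 in GV oocytes, with Pou5f1, Sox2, Tfap2c, Prdm14, Tbx3 and Dppa4 marked in c34 only. Meiosis genes were marked in 11 and 9 cases, with Prdm9 and Sycp1 in c34 only. Germline genes were marked in 6 and 3 cases, with Taf7l, Tex19.1 and Tdrd9 in c34 only. Of the chromatin machinery, 5 and 3 genes were marked, Dnmt3a, Pcgf1 and Nsd1 in c34 only and Kmt2a in GV oocytes only. Of the ovarian somatic genes, 16 were marked in c34 and 11 in GV oocytes. Foxl2, Fst, Wnt4 and Nr2f2 were marked at every stage, and Amhr2, Cyp11a1, Tcf21, Nr5a1 and Kitl in c34 and not in GV oocytes. Housekeeping genes were marked in 5 cases in c34, Hspa8, Rpl13a, Actb, B2m and Rplp0, and in 0 in GV oocytes.

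Over all protein-coding genes, 5527 were marked by H3K27me3 at both stages, 3925 in c34 only and 590 in GV oocytes only. The marked shares were 43.7% in c34 and 28.3% in GV oocytes, against 42.3% and 32.9% after random shifts. Marked genes were thus no more frequent than random placement gives, which limits what a call at a single gene shows. Of the GV H3K27me3 length, 76.8% lay in c34 peaks, a share that 0 of 1000 random shifts reached. The Jaccard index of c34 was 0.506 ± 0.0171 with GV oocytes and 0.419 ± 0.0148 with E18.5 oocytes, a difference of 0.0869 (0.0520 to 0.122) whose interval excluded 0. The c34 list was the longer, with a log2 ratio over GV of 0.36 (0.25 to 0.48).

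H3K36me3 gave the closest match of c34 with GV oocytes. All 15 genes with maternal germline imprinting had marked bodies in c34 and 13 had them in GV oocytes, Zdbf2 and Snrpn being marked in c34 only. Since this list is defined by methylation in the maternal germline, its number in GV oocytes may not be an independent result. Of the oocyte factors, 23 were marked in c34 and 18 in GV oocytes. Gdf9, the oocyte growth factor gene, Npm2, Ooep, Sohlh1 and Sohlh2 were marked in c34 only. At Gdf9 (chromosome 11, 53430774 to 53437904), 100% of the body was covered in c34 and 0% in GV oocytes. This gene lies within a single step of the 10 kb grid of these peaks, so no value in between was possible. Calls for other genes shorter than the grid are similarly coarse. The chromatin machinery was marked in 20 of 22 cases and the housekeeping genes in 19 of 20 cases at both stages, with no member differing. Genes with H3K27me3-dependent imprinting were marked in 6 cases in c34 and 1 in GV oocytes, Tle3, Smoc1, Bbx, Jade1 and Sall3 in c34 only.

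Meiosis genes had marked bodies in 18 cases in c34 and 16 in GV oocytes. Hormad1, Hormad2, Meioc, Msh5 and Tex15 were marked in c34 only, and Sycp1, Mei1 and Tex11 in GV oocytes only. Germline genes were marked in 12 and 11 cases, Tex19.1 in c34 only. Pluripotency and early germ cell genes were marked in 11 and 8 cases, Dppa2, Dppa3, Dppa4, Dppa5a and Pou5f1 in c34 only and Zfp42 and Prdm1 in GV oocytes only. Developmental regulators were marked in 6 and 4 cases, Gsc and Pax6 in c34 only. Ovarian somatic genes were marked in 8 and 11 cases. Foxl2, Cyp11a1, Wnt4, Kitl and Fshr were marked in GV oocytes only, and Inha and Cyp19a1 in c34 only.

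In total 12328 gene bodies were marked in both c34 and GV oocytes, 1397 in c34 only and 1132 in GV oocytes only. The widest c34 peak, 2740 kb on chromosome 14 (28790001 to 31530000, over Cacna2d3 and Cacna1d), lay over the second widest GV peak, 2400 kb (28730001 to 31130000). Of the c34 length, 85.2% lay in GV peaks. The Jaccard index was 0.698 ± 0.0157 with GV oocytes and 0.203 ± 0.0174 with E18.5 oocytes, and the difference of 0.495 had an interval of 0.440 to 0.549. The log2 ratio of covered length was -0.10 (-0.17 to -0.04). The E18.5 H3K36me3 list lay in genes no more than random placement, as given above, which bears on the index with it.

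**Figure D3:**
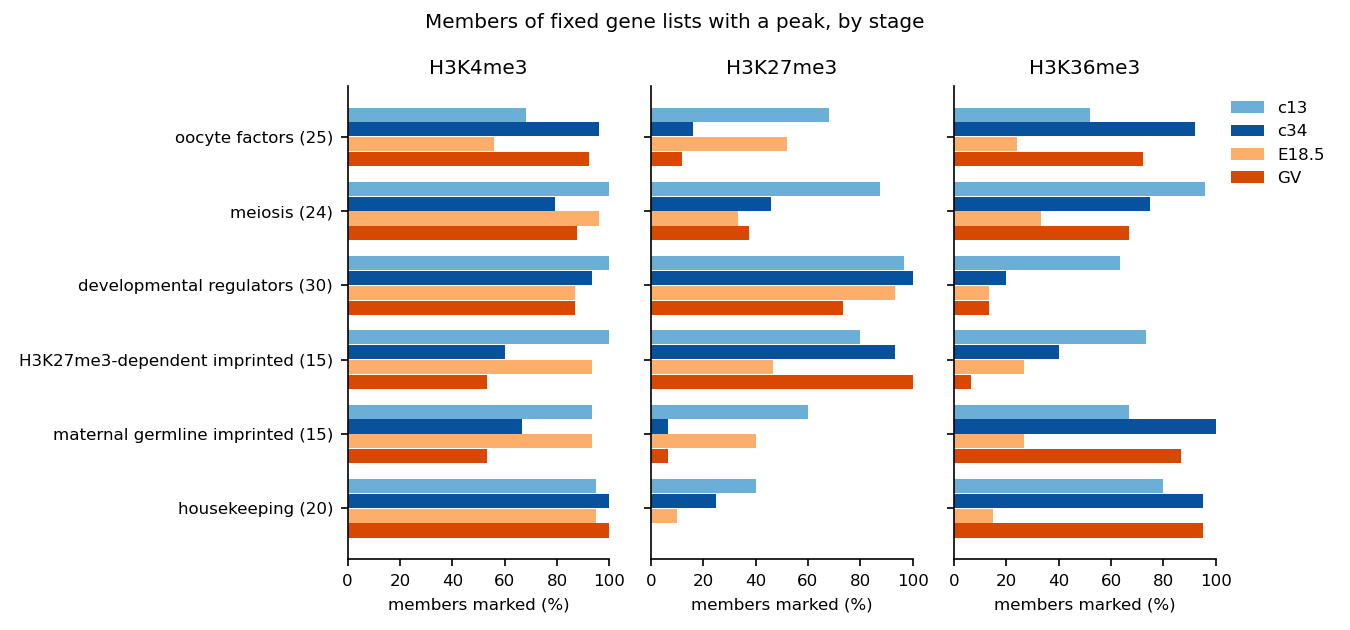
Bars give the percentage of members of 6 gene lists that were marked, by stage (colour) and mark (panel), with list sizes in parentheses. Oocyte factors were marked by H3K4me3 in 24 of 25 cases in c34 and 23 in GV oocytes, and genes with H3K27me3-dependent imprinting by H3K27me3 in 15 of 15 cases in GV oocytes and 7 at E18.5.

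The earlier oocyte-like stage, c13, was compared with E18.5 oocytes. Nearly every gene marked by H3K4me3 in E18.5 oocytes was also marked in c13: 13096 genes were marked in both, 158 at E18.5 only and 2406 in c13 only. All 24 meiosis genes were marked in c13 and 23 at E18.5, where Stra8, the gene for the retinoic acid-induced gatekeeper of meiosis, was not. Random lists gave 19.2 and 16.6. Of 16 germline genes, the same 15 were marked at both stages. Of the oocyte factors, 17 were marked in c13 and 14 at E18.5, with Zp1, a zona pellucida gene, Padi6 and Bcl2l10 in c13 only. Of the pluripotency and early germ cell genes, 19 were marked in c13 and 14 at E18.5, with Tbx3, Dppa3, Pou5f1, Esrrb and Tdgf1 in c13 only.

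Developmental regulators carried H3K4me3 in 30 cases in c13 and 26 at E18.5, with T, Gata4, Tbx5 and Hoxb1 in c13 only. Genes with maternal germline imprinting were marked in the same 14 cases at both stages, and those with H3K27me3-dependent imprinting in 15 and 14 cases, Runx1 in c13 only. The chromatin machinery was marked in 21 and 20 cases, Dnmt1 and Dnmt3l in c13 only and Dnmt3a at E18.5 only. The ovarian somatic genes were marked in 15 and 10 cases. Upk3b, Tcf21, Pdgfra, Gata4, Lhcgr and Fshr were marked in c13 only, and Cyp11a1 at E18.5 only. The same 19 housekeeping genes were marked at both stages. The largest E18.5 excess was at Ttn, the titin gene, with 19443 bp of its end windows covered at E18.5 and 1979 bp in c13, followed by Arpc5, Pabpc1, Cd3g and Rheb. In the opposite direction 42 genes tied at 20000 bp in c13 and 0 bp at E18.5, led in alphabetical order by Ackr2, Btbd17 and Card14.

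The H3K4me3 Jaccard index of c13 was 0.320 ± 0.00632 with E18.5 oocytes and 0.152 ± 0.00933 with GV oocytes, a difference of 0.168 (0.139 to 0.196). The c13 list covered more than the E18.5 list, with a log2 ratio of 0.91 (0.77 to 1.05). Both intervals excluded 0.

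For H3K27me3, 60.2% of all protein-coding genes were marked in c13 and 39.1% at E18.5, and the difference for meiosis genes was larger. Of 24 meiosis genes, 21 were marked in c13, against 15.3 in random lists, and 8 at E18.5, with Bhmg1 (Meiosin), Dmc1, Hormad2, Msh4, Msh5, Spo11, Stra8 and Rec8 among those in c13 only. The difference of -13 members lay at percentile 0.940 of those in random lists. It was not particular to meiosis genes, since 97 genes of the ribosomal protein family differed by -43, at percentile 0. This family was taken by symbols that begin with Rpl or Rps and a digit. That rule can also take other genes, such as those with Rps6k symbols, here and wherever ribosomal protein genes are counted. In c13, 23 of the 24 meiosis genes were also marked by H3K36me3. Germline genes were marked in 12 and 5 cases, at percentile 4.89, with Dazl, Ddx4, Piwil2 and Mov10l1 among those in c13 only. Pluripotency and early germ cell genes were marked in 15 and 6 cases, at percentile 3.66. Kit, Prdm1, Prdm14 and Tfap2c were among those in c13 only. Oocyte factors were marked in 17 and 13 cases, a difference at percentile 68.2 that random lists shared. Figla, Sohlh1, Kit and Ooep were among those in c13 only, and Nlrp14, Bmp15 and Nobox were marked at E18.5 only. Genes with H3K27me3-dependent imprinting were marked in 12 and 7 cases, at percentile 28.8, with Enc1, Sfmbt2, Smoc1, Bbx and Inhbb in c13 only.

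Developmental regulators were marked by H3K27me3 in 29 cases in c13 and 28 at E18.5, with Gata6 and Lhx2 in c13 only and En1 at E18.5 only. Genes with maternal germline imprinting were marked in 9 and 6 cases, Plagl1, Mcts2 and Igf2r in c13 only. The chromatin machinery was marked in 13 and 5 cases, and Kdm6a, an X-linked H3K27 demethylase gene, at E18.5 only. Ovarian somatic genes were marked in 17 and 16 cases, and housekeeping genes in 8 and 2. In the order named here, these differences lay at percentiles 87.8, 51.3, 16.4, 87.1 and 20.7 of random lists. Over all protein-coding genes, 6333 were marked at both stages, 6699 in c13 only and 2114 at E18.5 only.

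The H3K27me3 Jaccard index of c13 was 0.394 ± 0.0200 with E18.5 oocytes and 0.310 ± 0.0143 with GV oocytes, a difference of 0.0841 (0.0363 to 0.132). This order did not hold for overlap beyond chance, which takes the covered lengths into account and gave a difference of -0.0199 (-0.0991 to 0.0593). Covered length did not differ detectably between c13 and E18.5, with a log2 ratio of 0.03 (-0.17 to 0.22), and the ratio was -0.40 without peaks of 1 Mb or more.

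H3K36me3 in c13 shared little with E18.5 oocytes. Marked bodies numbered 2787 in both, 11887 in c13 only and 1999 at E18.5 only. At E18.5, 22.1% of bodies were marked, against 25.8% after random shifts. Of the meiosis genes, 23 were marked in c13 and 8 at E18.5, with Dmc1, Hormad1, Mael and Majin among those in c13 only and Tex11 at E18.5 only. Of the housekeeping genes, 16 were marked in c13 and 3 at E18.5, with Actb, B2m, Eif4a1 and Gapdh among those in c13 only and the X-linked Hprt and Pgk1 at E18.5 only. Oocyte factors were marked in 13 and 6 cases, with Nlrp5, Nobox, Zar1 and Oosp1 at E18.5 only. Germline genes were marked in 14 and 7 cases, pluripotency and early germ cell genes in 11 and 1, developmental regulators in 19 and 4, and chromatin machinery in 15 and 3. Genes with H3K27me3-dependent imprinting were marked in 11 and 4 cases, those with maternal germline imprinting in 10 and 4, and ovarian somatic genes in 13 and 5.

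The H3K36me3 Jaccard index of c13 was 0.195 ± 0.0317 with E18.5 oocytes, where 134 of 1000 random shifts gave an overlap as large, and 0.433 ± 0.0185 with GV oocytes. The difference of -0.238 (-0.311 to -0.165) became 0.0326 when peaks of 1 Mb or more were left out and 0.0214 for peaks with 50% reciprocal overlap. The log2 ratio of covered length, 0.82 (0.45 to 1.20), became -0.87 without those wide peaks. These counts do not separate differences between the cells from differences in the quality of the lists, which was not measured.

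Late and early stages were then compared within culture and within animals, to ask whether the same genes differed. A gene marked at the later stage alone is said to have gained the mark, and a gene marked at the earlier stage alone to have lost it. Between c13 and c34, 7 oocyte factors gained H3K4me3 and 0 lost it, a net number at percentile 100 of random lists. They were Bmp15, an oocyte growth factor gene, H1f8, Oosp1, Nlrp5, Khdc3, Npm2 and Oog1. Between E18.5 and GV oocytes 9 gained it, at percentile 99.2, with Khdc3, Oosp1, Bmp15, H1f8 and Nlrp5 again among them. Over the same intervals H3K27me3 was lost from 14 oocyte factors and gained at 1 in culture, and lost from 13 and gained at 3 in animals. The net numbers, -13 and -10, lay at percentiles 0.0350 and 0.630. Zp1, Zp2 and Zp3, the zona pellucida genes, Kit, Oosp1, Padi6, Tle6 and H1f8 were among those without the mark in c34. The loss in culture was not particular to oocyte factors. Ribosomal protein genes had a net number of -41 in culture, at percentile 0, and of -12 in animals, at percentile 50.6. Gene body H3K36me3 was gained by 10 oocyte factors in culture, Bmp15, Kit, Nlrp5 and Nobox among them, and lost by 0. In animals 13 gained it and 1, Npm2, lost it. The net number lay at percentile 100 in culture and 74.5 in animals, where random lists also gained H3K36me3.

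Genes with H3K27me3-dependent imprinting lost H3K4me3 over both intervals, 6 of 15 in culture and 6 in animals, with 0 gained. The net numbers lay at percentiles 0.120 and 0. Otx2, Prox1, Slc38a4 and Sfmbt2 were common to both, Runx1 and Jade1 lost it in culture only, and Etv6 and Inhbb in animals only. Genes with maternal germline imprinting lost H3K4me3 as well, in 4 of 15 cases in culture (Mcts2, Zdbf2, Plagl1 and Nap1l5) and 6 in animals (Mcts2, Nnat, Peg3, Nap1l5, Zrsr1 and Plagl1), with 0 gained, at percentiles 2.00 and 0. H3K27me3 was gained at 8 of the genes with H3K27me3-dependent imprinting between E18.5 and GV oocytes, Bbx, Gab1, Rbms1, Sfmbt2, Smoc1, Inhbb, Enc1 and Jade1, with 0 lost, at percentile 100. The GV state follows in part from how the list is defined, so that percentile is no independent result. The same limit bears on the H3K4me3 loss of this list in animals. In GV oocytes H3K4me3 and H3K27me3 shared less length than independent placement would give, at a ratio of 0.574. Genes with maternal germline imprinting are also defined by an oocyte state, DNA methylation. Their percentiles in animals may therefore not be independent of that definition. Between c13 and c34, Rbms1, Gab1 and Jade1 gained H3K27me3 and Bbx lost it, at percentile 98.5. At Sfmbt2 (chromosome 2, 10370440 to 10595253), H3K27me3 peaks covered 20000 bp of the end windows in c13, c34 and GV oocytes and 0 bp in c7 and at E18.5. Genes with maternal germline imprinting lost H3K27me3 in 8 of 15 cases in culture, Grb10, Peg10, Zdbf2, Gnas, Nnat, Mcts2, Mest and Igf2r, at percentile 0.380. Their bodies gained H3K36me3 in 5 cases, Nap1l5, Peg10, Plagl1, Zdbf2 and Snrpn, at percentile 99.5. In animals 6 lost H3K27me3, Grb10, Peg10, Nnat, Mest, Zdbf2 and Gnas, and Plagl1 gained it, at percentile 6.75, and 10 bodies gained H3K36me3 while Zdbf2 lost it, at percentile 88.8.

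Some meiosis and pluripotency genes were marked by H3K4me3 at only the earlier or only the later stage. Rec8, Spo11, Syce3, Stag3 and Tex11 were marked in c13 and not in c34, and Tex11, Stag3 and Syce1 at E18.5 and not in GV oocytes, where Stra8 gained it. Fgf4, Utf1, Nanog, Esrrb and Tdgf1 were marked in c13 and not in c34, where Dppa2 gained the mark. In animals Nanog lost the mark, and Dppa3, Tbx3, Pou5f1, Dppa2 and Tdgf1 gained it. Zfp42, Nanog and Dppa3 gained H3K27me3 both between c13 and c34 and between E18.5 and GV oocytes, and Lin28a lost it over both. Kit, Prdm1, Tcl1 and Dppa5a also lost it in culture and Tbx3 in animals. The chromatin machinery gained H3K36me3 at 6 genes in culture, Kdm1b, Kdm5b, Rnf2, Eed, Ezh2 and Kmt2a, and lost it at Tet1, at percentile 98.2. In animals 18 of 22 gained it, Kdm1b and Kdm5b among them, and Kdm6a lost it, at percentile 99.6. Housekeeping genes gained it likewise in animals, in 16 of 20 cases at percentile 99.9, beside an E18.5 list that lay in genes no more than random placement. The largest c34 excess of H3K4me3 over c13 was at Folr1, a folate receptor gene, Prok2, Smim9, Gm30679 and Peli1, and genes with the largest E18.5 excess over GV oocytes included Ttn, Cep95 and Hsf1.

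Wide H3K4me3 domains differed between the intervals. Peaks of 5 kb or more held 84.0% of the H3K4me3 length in c13, 84.3% in c34, 74.8% at E18.5 and 97.0% in GV oocytes. Peaks of 50 kb or more numbered 579, 36, 1 and 2141. The rise of 22.2 percentage points from E18.5 to GV oocytes (20.6 to 23.7) exceeded the difference of 0.285 points in culture (-2.29 to 2.87), which was not detectable, by an interval that excluded 0 (-21.9, -23.5 to -20.2). The culture difference was -13.0 points (-17.6 to -8.31) for domains of at least 10 kb, so its sign rested on the width chosen. The Jaccard index of c13 and c34 was 0.231 for H3K4me3, 0.509 for H3K27me3 and 0.448 for H3K36me3, and that of E18.5 and GV oocytes 0.0978, 0.303 and 0.209. For H3K4me3 the covered lengths at E18.5 and in GV oocytes allowed at most 0.210, and overlap beyond chance had the opposite order, 0.311 in culture and 0.354 in animals.

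H3K27me3 was also mapped in c7 oogonia-like cells. Of 21631 protein-coding genes, 7936 were marked in both c7 and c13, 2020 in c7 only and 5096 in c13 only. In c7 the marked share was 46.0%, against 40.3% after random shifts. Pluripotency and early germ cell genes were marked in 6 of 20 cases in c7 and 15 in c13, a net gain of 9 at percentile 99.5 of random lists. Kit, Prdm1, Prdm14, Tfap2c, Tcl1, Pou5f1, Sox2 and Utf1 were marked in c13 only. Ribosomal protein genes likewise had a net gain of 30, at percentile 100. Meiosis genes were marked in 14 cases in c7 and 21 in c13, with Spo11, Stra8, Syce1 and Rec8 among the additions and Tex11 in c7 only. That net gain of 7 lay at percentile 83.0, where random lists gained 4.42. Oocyte factors were marked in 15 and 17 cases, germline genes in 11 and 12, and developmental regulators in 30 and 29, En1 being marked in c7 only. Their net numbers lay at percentiles 30.6, 33.2 and 10.9. Genes with H3K27me3-dependent imprinting were marked in 8 and 12 cases, with Enc1, Sfmbt2, Slc38a4 and Bbx the additions, and those with maternal germline imprinting in 8 and 9. These net numbers lay at percentiles 72.3 and 29.9. The chromatin machinery was marked in 5 and 13 cases, ovarian somatic genes in 16 and 17, and housekeeping genes in 4 and 8, at percentiles 94.3, 24.5 and 75.7.

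The widest c7 domain, 2980 kb on chromosome 5 (118150001 to 121130000) over the limb and heart regulators Tbx3 and Tbx5, lay inside the widest c13 domain, 5510 kb (115620001 to 121130000). The Irx1, Irx2 and Irx4 cluster on chromosome 13 lay in 1 of the 3 widest domains of both c34 (71350001 to 73460000) and E18.5 oocytes (70640001 to 73470000). The widest GV domain, 2710 kb on chromosome 17 (88730001 to 91440000), held the gonadotropin receptor genes Lhcgr and Fshr. Of the c7 length, 68.0% (63.3 to 72.6) lay in c13 peaks, and of the c13 length 63.5% (61.1 to 65.8) lay in c34 peaks. The former share was 45.5% without peaks of 1 Mb or more. The Jaccard index of c7 was 0.453 with c13, 0.423 with c34, 0.490 with E18.5 oocytes and 0.301 with GV oocytes.

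Marks were also compared within a stage. Genes marked by both H3K4me3 and H3K27me3 numbered 10808 in c13, 5740 in c34, 4287 at E18.5 and 3705 in GV oocytes, where independent marks would give 9339, 6307, 5176 and 4575. Of 30 developmental regulators, 29 carried both marks in c13, 28 in c34, 24 at E18.5 and 18 in GV oocytes. Of the GV genes with both marks, 68.9% also had both in c34, 2554 genes where independence would give 983. Of the E18.5 genes 86.2% also had both in c13, 3697 where independence would give 2142, a high base since 10808 genes had both in c13. The numbers rested on the window at either gene end. With a peak required at both ends they were 4753, 1245, 882 and 1134, and GV oocytes then had more than E18.5 oocytes. With equal numbers of peaks c34 had 3253, fewer than the 3813 at E18.5.

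By length, all 3 marks overlapped in c13 more than independent placement would give. The ratio of observed to independent shared length was 1.87 for H3K4me3 with H3K27me3, 2.04 for H3K4me3 with H3K36me3 and 1.75 for H3K27me3 with H3K36me3. In c34 these ratios were 0.853, 1.67 and 0.610, at E18.5 0.905, 0.815 and 1.16, and in GV oocytes 0.574, 0.733 and 0.397. The c13 lists of H3K27me3 and H3K36me3 had a Jaccard index of 0.572, so genes named above as marked by either in c13 often lay in both.

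**Figure D4:**
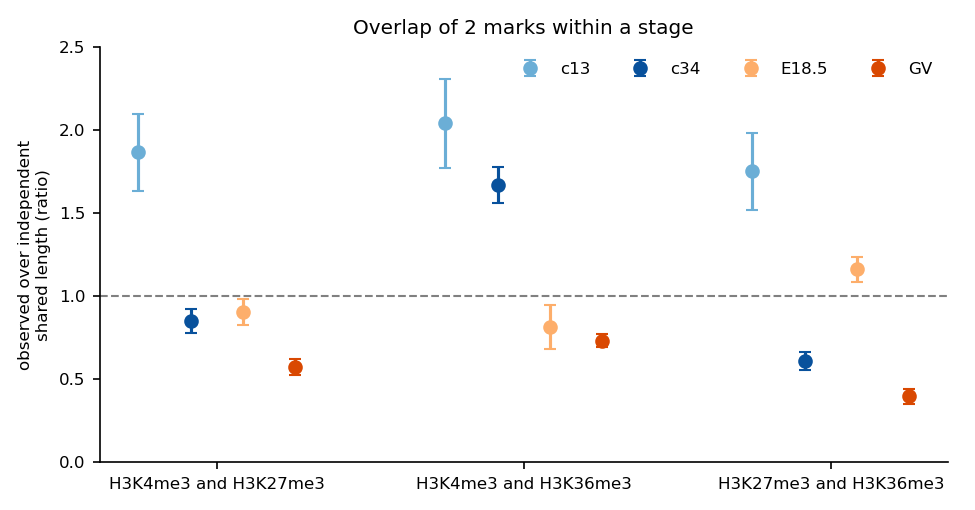
Points give the ratio of observed to independent shared length for each pair of marks within a stage, with 95% jackknife intervals and a dashed line at 1. All 3 pairs lay above 1 in c13 (1.87, 2.04 and 1.75) and below 1 in GV oocytes (0.574, 0.733 and 0.397).

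Of the widest H3K4me3 peaks, those over Prdm1 recurred between lists. At E18.5 the widest was 197 kb on chromosome 10 (44401001 to 44598000) over Prdm1, the gene of a germ cell transcription factor and of a reporter in these animals, and the next was 47 kb over Hoxa3 to Hoxa11 on chromosome 6 (52200001 to 52247000). The widest c34 peak, 96 kb (44408001 to 44504000), also lay over Prdm1, and c13 had a 234 kb peak there. GV oocytes, which had no reporter label, covered 33.0% of the E18.5 peak, c34 77.7% and c13 100%. The other widest c34 peaks were 89 kb over Unc13a and Jak3 on chromosome 8 (71641001 to 71730000) and 83 kb over Sfi1 on chromosome 11 (3123001 to 3206000). The widest GV peak was 239 kb on chromosome 16 (23855001 to 24094000) over Sst, Rtp2 and Bcl6, followed by 234 kb over Ercc6l2 and 227 kb over the tight junction gene Tjp1. In c13 it was 613 kb on chromosome 11 (119708001 to 120321000), over 9 genes including Rptor, Chmp6 and Baiap2.

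**Figure D5:**
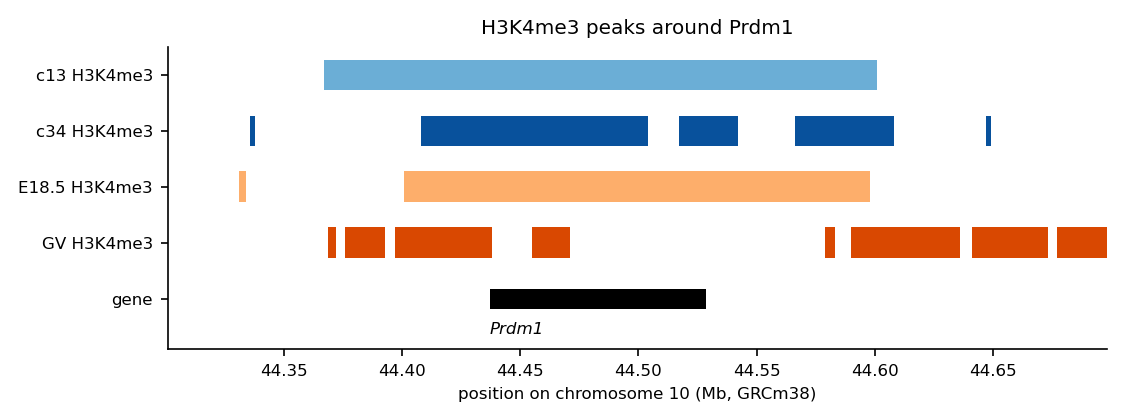
Bars show H3K4me3 peaks by stage and the Prdm1 gene along chromosome 10 (Mb, GRCm38). A 234 kb peak in c13 and a 197 kb peak in E18.5 oocytes span the whole gene, while the widest GV peak that touches the gene is 41 kb.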

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

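The tests of explanations in this part were chosen after the results were seen, and so were the contrasts of late and early stages in culture with those in animals, except that for the share of H3K4me3 in wide peaks. The difference between c34 and c13 was set against that between GV and E18.5 oocytes for 7 measures, and in all 7 the jackknife interval of the difference excluded 0. H3K4me3 covered length differed by a log2 ratio of 0.03 in culture and 2.25 in animals, a gap of -2.23 (-2.34 to -2.11). Its share in protein-coding genes differed by -15.2 and -30.4 points, a gap of 15.3, and its share in peaks of 5 kb or more by 0.285 and 22.2 points, a gap of -21.9. H3K27me3 covered length differed by log2 ratios of -0.18 and -0.52, a gap of 0.34, and its share in genes by -7.26 and 3.02 points, a gap of -10.3. H3K36me3 covered length differed by log2 ratios of -0.27 and 0.65, a gap of -0.93, and its share in genes by 9.79 and 22.8 points, a gap of -13.0. Without peaks of 1 Mb or more, the gap in covered length was 0.77 (0.55 to 0.99) for H3K36me3, of opposite sign, and 0.76 (0.58 to 0.94) for H3K27me3, and the gaps in share of genes were -16.3 and -11.2 points. The c13 H3K4me3 list held 7 peaks on the Y chromosome, above the counting limit of 3 for a count of 0, a limit that says nothing of their origin. Of them 6 lay beyond 90 Mb, where all 4 H3K4me3 lists had a peak from 90767001 to 90770000.

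The 197 kb H3K4me3 peak over Prdm1 in E18.5 oocytes was wider than the next, 47 kb, and peaks of 234 kb in c13 and 96 kb in c34 lay at the same gene. Cells with the Prdm1 reporter may carry extra copies of the region, which would raise reads of every kind there. GV oocytes, without a reporter label, covered 33.0% of the block with H3K4me3, below their 51.4% of the remaining E18.5 length, which would go with that explanation. Against it, 6 of 7 H3K27me3 and H3K36me3 lists of cells with the reporter covered 0% of the block. The exception was c13 H3K27me3 with 100%. In GV oocytes H3K36me3 covered 76.1% of the block, but H3K27me3 covered 0% there too. Dppa3, the other reporter gene, had no H3K4me3 peak at E18.5, 27 kb peaks in c13 and c34 and the widest, 41 kb, in GV oocytes. Because thresholds and use of input are unknown, reporter, strain and stage cannot be told apart here, and a biological width of the domain in early germ cells remains open and untested.

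In c13, H3K36me3 and H3K27me3 peaks lay together. A shared preference for gene-dense regions would leave a ratio near 1 within regions of like gene density, but it was 1.45 (1.32 to 1.58), which argues against gene density as the whole cause. H3K27me3 in place of H3K36me3 throughout the list is argued against too, since its Jaccard index was larger with c34 H3K36me3 (0.448) than with c34 H3K27me3 (0.372), by 0.0762 (0.0456 to 0.107), although a partial mixture was not tested. A background shared by all 3 c13 lists may contribute: H3K4me3 also overlapped both marks in c13 beyond independent placement within density groups, with a lower interval end of 1.37 for the pair with the lower ratio, H3K4me3 with H3K27me3, which had 0.769 in c34. The ratio of H3K4me3 with H3K36me3 was 1.56 in c13 but also above 1 in c34, at 1.39, so it says less. Mixed cell populations in c13, a biological explanation, were not tested.

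The X chromosome was covered less than the autosomes in every list of the H18 line, with ratios from 0.131 for c13 H3K27me3 to 0.487 for c34 H3K36me3, and in all 7 lists this ratio was lower than in both lists from animals of that mark. With regions matched on gene density this held for 6 of 7, since c7 H3K27me3 had 0.476 and GV H3K27me3 0.467. With this matching, the X lay below every autosome in the 6 c13 and c34 lists, at most 0.784 of the lowest autosome, which argues against few genes as the cause there, while in c7 it was 1.03 of the lowest autosome and this stays open. The X also lay below every autosome at E18.5 for H3K4me3 and in GV oocytes for H3K27me3, so the line is not the sole setting. Fewer X copies in the line could give lower coverage. The count of lists that lay that way, 7 of 7 unmatched and 6 of 7 matched, restates the pattern and is no test of this. By the share of genes marked, X over autosomes, it was also 6 of 7, with c13 H3K4me3 at 0.725 and E18.5 at 0.702, and line, culture and strain cannot be told apart. The H3K27me3 ratio differed between stages of this same line, 0.455 in c7, 0.131 in c13 and 0.297 in c34, and a stage-dependent state of the X was not tested.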

How the results depend on the processing

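Requiring both gene ends, genes apart from others, wider merging, overlap beyond chance and leaving out peaks of 1 Mb or more were chosen after seeing the data. Of 102 alternatives for the 15 differences, 93 kept direction and side of 0 (23 of them unable to change by construction, which says nothing of stability), 3 passed from not called to called and 6 changed sign, 2 of these with intervals that held 0, 2 from a call to the opposite call and 2 from no call to a call; of 78 for counts, 58 stayed within 1.5 times (2 of them unable to change), and of 6 for shares, 3 did not move beyond their interval. With peaks at or above the median width, the broad domain difference of c34 and c13 was 4.51 points, genes with H3K4me3 numbered 3466 in c34 only and 3677 in GV only, genes with both marks 2888 in c34, 2216 at E18.5 and 1586 in GV, and c13 H3K27me3 kept in c34 was 60.3%. With equal numbers of peaks, H3K4me3 in c34 only was 927, and both marks 3253 in c34 and 2399 in GV, with 3813 at E18.5. With 50% reciprocal overlap, the H3K36me3 difference of c13 between E18.5 and GV was 0.0214 (-0.0318 to 0.0745). The broad domain difference was 0.627 from 2 kb, -13.0 from 10 kb and 0.853 after merging within 20 or 100 kb. With both ends required, H3K4me3 in c34 only was 1289, and both marks 4753 in c13, 1245 in c34, 882 at E18.5 and 1134 in GV. Among 11560 genes apart from others, genes in c34 only numbered 297 for H3K4me3, 2145 for H3K27me3 and 780 for H3K36me3, and both marks 4747 in c13, 2810 in c34, 2240 at E18.5 and 1913 in GV, lower since fewer genes were counted. Overlap beyond chance gave -0.0199 for H3K27me3 of c13. Without peaks of 1 Mb or more, log2 covered c13 over E18.5 was -0.40 for H3K27me3 and -0.87 for H3K36me3, the H3K36me3 difference of c13 was 0.0326, c7 H3K27me3 kept in c13 was 45.5%, c13 kept in c34 59.4%, and the contrast of culture with animals for H3K36me3 covered length 0.77 in place of -0.93. Apart from the lower number of genes, the cause was not tested. Merging within 3 kb changed nothing, since no gap was that small. Every transcript start was not run because the gene table holds none. No paired analysis was possible because each stage and mark had 1 list, and leaving out a replicate was not possible for the same reason. Unknown depth limits every covered length and count.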

Other observations

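The test in this part was chosen after the result was seen. Gene families fixed by symbol differed in their marks. Members of a family can be neighbours in a cluster, so a wide peak can mark many of them at once. Random lists of scattered genes do not allow for this, and the numbers of members are not independent counts. Of 39 Hox cluster genes, 39 were marked by H3K27me3 in c7, c13, c34 and at E18.5 and 37 in GV oocytes, and 39, 37, 38 and 37 by H3K4me3 in c13, c34, E18.5 and GV oocytes. Their bodies had H3K36me3 in 19 cases in c13 and in 0 at the other stages. Of 57 clustered protocadherin genes, which encode neuronal adhesion proteins, H3K27me3 marked 56 in c7, 47 in c13, 52 in c34, 57 at E18.5 and 38 in GV oocytes, and H3K4me3 marked 41 in c13, 21 in c34, 7 at E18.5 and 46 in GV oocytes. Of 49 keratin genes, 49 had H3K27me3 in c13 and in c34, 48 in c7 and at E18.5 and 31 in GV oocytes, and bodies with H3K36me3 numbered 49 in c13, 4 in c34, 0 at E18.5 and 10 in GV oocytes. Of 33 Rhox genes, an X-linked homeobox cluster, 28 had H3K27me3 in GV oocytes, where random lists gave 9.33, against 17 in c34, 10 at E18.5, 5 in c7 and 1 in c13.

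Of 1106 olfactory receptor genes, H3K27me3 marked 510 at E18.5, 451 in c7, 289 in GV oocytes, 248 in c34 and 145 in c13. H3K4me3 marked 176 in GV oocytes and at most 42 at the other stages. The net H3K4me3 number from E18.5 to GV oocytes, 156, was near the 154 of random lists, at percentile 55.2. In GV oocytes 74.8% of all protein-coding genes were marked, so this family had few marked members for that stage. Of 353 vomeronasal receptor genes, H3K36me3 covered 140 bodies at E18.5, where random lists gave 70.7, against 31 in c13, 55 in c34 and 54 in GV oocytes, and H3K27me3 marked 84 in c7, 3 in c13, 32 in c34, 115 at E18.5 and 42 in GV oocytes. Of 97 ribosomal protein genes, H3K27me3 marked 33 in c7, 63 in c13, 22 in c34, 20 at E18.5 and 8 in GV oocytes, and H3K36me3 covered 84, 86, 13 and 85 bodies in c13, c34, E18.5 and GV oocytes. Of 67 histone genes, H3K4me3 marked 62 or 63 at every stage and H3K27me3 33 in c7, 27 in c13, 11 in c34, 13 at E18.5 and 1 in GV oocytes. Of 367 Zfp zinc finger genes, H3K4me3 marked 334, 315, 302 and 318 in c13, c34, E18.5 and GV oocytes, and H3K27me3 163, 99, 105 and 56, with 135 in c7.

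GV oocytes had 449 Mb of H3K4me3 outside the c34 H3K4me3 peaks, and 51.7% of it lay in c34 H3K27me3 peaks, against 32.4% of the remaining length, a difference of 19.3 points (17.7 to 21.0). In GV oocytes 17.9% of it lay in H3K27me3 peaks. Avoidance of genes and of c34 H3K36me3 by both lists would leave no such difference outside them. Outside protein-coding genes and c34 H3K36me3 the difference was 13.8 points (10.8 to 16.8, with 49.0% against 35.2%), which argues against that avoidance as the whole cause. GV H3K36me3, which GV H3K4me3 avoided more (ratio 0.733) than c34 H3K36me3 (0.818), was not removed. Nor was length where no peak could be called, so other shared avoidance was not tested. The lists come from different cells, strains and depths, and no order of events was tested.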
